A study of Pimephales promelas with 8 samples.

How the data were processed

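Gene expression was measured in whole brains of fathead minnow (Pimephales promelas), a small fish used as a test species in ecotoxicology. Per the labels, 8 reproductive adults were used, 4 kept in solvent control water and 4 kept for 21 days in water with 10 ug/L propranolol (spelled propanolol in the labels), and the design text describes them as males and as different fish. Each brain gave 1 sample. Per the labels' protocols, Cy3-labelled cRNA was made from total RNA with a one-colour Agilent low-input kit. Each of the 8 samples was hybridised to its own one-colour Agilent array with 15208 non-control probes of 60 bases, each probe with 1 spot.

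The deposited scanner files hold spot intensity on a linear scale, 1 file per array. Per the file headers, the scans were read with Agilent Feature Extraction 10.1.1.1, while the submitters' processing notes name version 9.1. The cause of that difference is not given in the sources used here. Per the file headers, the processed intensity is corrected for background and for spatial trends within its array, and spots too dim to measure carry a substitute value. No scaling between arrays is recorded in the file headers. The files also hold quality flags for each spot (coded as other values), used here as deposited by the authors.

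The deposited value table of the whole series holds log2 values. Set against the scanner files, each of its columns equalled the log2 processed intensity minus the median over the non-control probes of that array, and the spots with a non-uniformity flag were empty. The median of each column was 0. Scale, centring and direction of that table were therefore settled from the files, and it served as an alternative starting point.

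From the scanner files, the log2 processed intensity minus the 75th percentile of the array over non-control probes was computed. Control spots and spots with an outlier flag were left out. A probe was tested when it was well above background on every array of at least 1 group, which 11406 of the 15208 probes were. Propranolol was compared with control by a two-sided moderated test per probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 8 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Counts were also taken at an unadjusted p under 0.05, with and without a fold of at least 1.5. A fold against a group in which a probe was not well above background on all arrays, or on 3 of 4, was also given as a lower bound or with dim spots raised. The dim group then had, on each dim array, the higher of the probe's own value and the lowest signal among probes well above background. It is a lower bound only if the true level of a dim spot was no higher than that. Values are on the log2 scale, so 1 unit is a 2-fold difference.

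The scripts were tested on simulated data made from the 11381 tested probes with a value on every array. The residuals of each probe were shuffled over the arrays, and 200 probes per run were changed by known folds in 20 runs. For the comparison of propranolol with control, 2% of probes changed 1.5-fold, 20.9% of those changed 2-fold, 73.7% of those changed 4-fold and 89.9% of those changed 8-fold were recovered at the adjusted threshold. False calls made up 6% of all calls. Each probe was shuffled on its own, which removes correlation between probes. The 200 changed probes also make the adjusted threshold easier to reach than where few probes change. These rates therefore need not hold for the real comparison.

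The arrays passed similar checks in both groups. Between 76.2% and 82.4% of probes were well above background on each array, no probe was saturated, and 1 to 8 spots per array carried an outlier flag. The slope of signal against the spiked-in amounts, as the file headers give it, lay between 0.976 and 1.01. All 8 arrays shared 1 slide, so a planned fit with slide or scan as a block could not be made. The slide had 2 rows of arrays, each with 2 control and 2 propranolol arrays, and row was used as a block after the data had been examined. Slide columns were not balanced: column 1 held only propranolol 2 and 4, and column 3 only controls 3 and 4. Columns 2 and 4 each held a control and a propranolol array. Column was not used as a block, so it is partly tied to the groups in every result. The number of arrays limits the precision.

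All 15208 probes were described as unknown. Their names were those of contigs (11862 probes), GenBank sequence numbers (3309 probes) or clones (37 probes). In the gene table of the RefSeq assembly fPimPro1.hap1.1, 0 of these names equalled a symbol or an accession. The files used here do not pair probes with genes, so 33 gene lists fixed before the data were examined, among them adrenergic receptors, the serotonin system, pituitary hormones and markers of other cell types, matched 0 probes. The gene list tests planned with camera and fry, and the check of cell type markers, were not run.

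The rule for named genes was also fixed before the data were examined. It took, among probes with a gene name, the largest folds in each direction past the adjusted threshold. Remaining places went to the largest folds at an unadjusted p under 0.05 whose 4 propranolol values did not overlap the 4 control values. With no gene names, it was applied without the name condition and stopped at 2 probes per direction. Its other parts, which name members of gene lists, could not be applied.

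The alternatives fixed before the data were examined were quantile normalization, median centring, normexp background correction on the mean and background intensities (offset 50) with quantile normalization, the deposited log2 table, no filter on dim probes, a filter asking for all 8 arrays, eBayes with trend and robust, array weights, an ordinary linear model per probe, a threshold of 0.10, the replicate number as a block, and leaving out each array in turn. Slide row as a block, each slide row alone and dim spots raised to the lowest well-above-background signal were added afterwards. A test of whole profiles was added afterwards as well. Its pseudo-F compares squared Euclidean distances between and within groups over the tested probes with a value on every array, and its exact p counts the splits of the 8 arrays into 4 and 4 with a pseudo-F as large, among 35. Probes were filtered by the real groups and kept for every split, here and in the other counts over splits. That can favour the real split, so p is strictly exact only with no filter or with the filter on all 8 arrays.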

Results

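Brain expression profiles were collected from 8 fathead minnows, 4 solvent controls and 4 exposed for 21 days to 10 ug/L propranolol, a non-selective beta-adrenergic receptor blocker used as a heart drug. The series set out to examine effects of the drug on reproductive behaviour and gene expression, and the arrays address the expression part. Each fish was measured on 1 array. The 75th percentile of the processed intensity ranged from 973 to 1632 over the arrays, with means of 1157 ± 154 in controls and 1349 ± 275 in propranolol fish (SD, n = 4 each). Between 11589 and 12527 of the 15208 probes were well above background on each array.

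Profiles of all fish were alike in the levels of probes relative to each other, which does not show that the groups were alike. Across the 11406 tested probes, arrays correlated with Pearson's r between 0.944 and 0.978, and the highest r was that of controls 1 and 2. Over all tested probes, the median change was 0.20 in absolute log2 units (1.15-fold), and 86.6% of probes differed by less than 1.5-fold between group means. A difference of 2-fold or more was seen in 510 probes (4.47%). The median SD among fish of a group was 0.30 log2 units in controls and 0.35 in propranolol fish, a difference that 8 of the 35 splits of the 8 arrays matched in size (exact permutation p = 0.229, two-sided).

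The question of whether exposed and control brains differed as whole profiles was put with a permutation test chosen after the data had been examined. The pseudo-F of propranolol against control was 1.46, with 19.6% of the squared distance lying between groups. It was the highest of the 35 splits (exact permutation p = 0.0286, the smallest this design allows), ahead of 1.43 for the next split. The median pseudo-F of the other splits was 0.955. Any split puts part of the squared distance between its groups, so the 19.6% is not a share tied to propranolol. Since the tested probes were filtered by the real groups, which can favour the real split, that p is not strictly exact. Under filters that do not use the groups, the exact permutation p was 0.171 (no filter) and 0.2 (well above background on all 8 arrays). Controls 1 and 2, the most alike pair, moved with this measure: pseudo-F was 1 to 1.46 in the 15 splits that kept them together and 0.688 to 1.17 in the 20 that parted them. Among the 15 splits alone the smallest exact permutation p possible is 0.0667, and without control 1 or control 2 the exact permutation p was 0.0571 each. Over 16 alternative settings the exact permutation p ranged from 0.0286 to 0.2, and it stayed under 0.05 in 5 of them. On the first principal component, which held 23.3% of the variance, controls lay from -50.9 to -0.225 and propranolol fish from -5.94 to 33.7, so that the groups overlapped at propranolol 1.

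**Figure D1:**
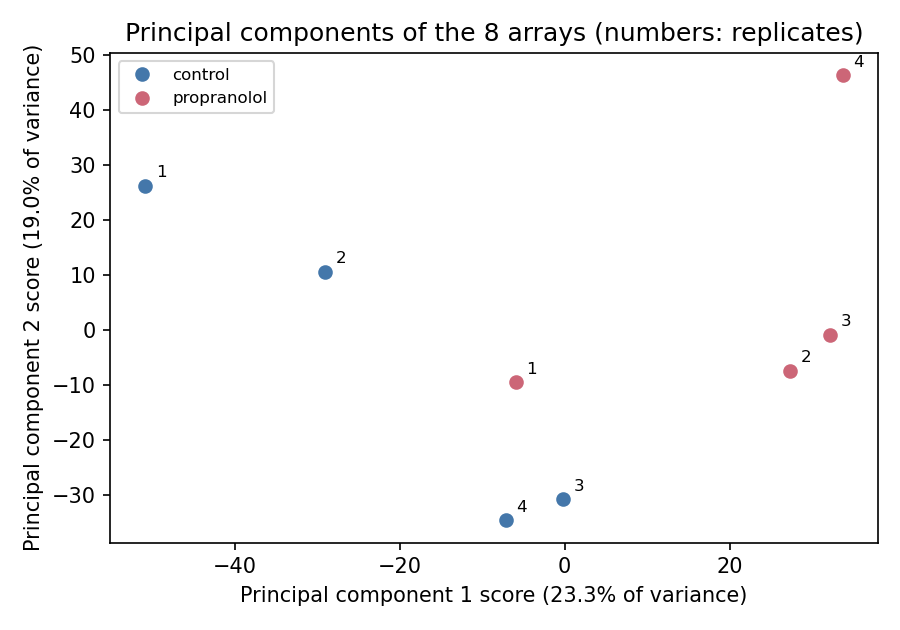
Scores of the 8 arrays on principal components 1 (horizontal) and 2 (vertical), in log2 units, computed from the tested probes with a value on every array. Points are single fish, coloured by group and numbered by replicate. Propranolol 2, 3 and 4 lie at 27.4, 32.1 and 33.7 on component 1, and propranolol 1 lies at -5.94, among the controls.

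Single probes gave few differences that passed adjustment. With limma and Benjamini-Hochberg adjustment, 1 of 11406 probes rose in propranolol fish and 0 fell. That probe was UF_Ppr_AF_102279, with a mean log2 intensity relative to the 75th percentile of -7.95 ± 1.5 in controls and -0.61 ± 0.75 in propranolol fish (SD, n = 4 each). Its log2 fold change was 7.34 with a standard error of 0.71 (limma, adjusted p = 0.0474), a size that rests on values not well above background in 3 controls. It was well above background in 4 of 4 propranolol fish and in 1 of 4 controls, and its processed intensity was 577 to 1730 in the former and 2.53 to 19.2 in the latter. With dim spots raised to the lowest well-above-background signal of each array, a setting chosen after the data had been examined, the log2 fold change was 5.77 (54.5-fold). That is a lower bound only if the true levels of the dim spots were no higher than that signal. With normexp, the log2 fold change was smaller, at 3.79. With dim spots raised, the probe was higher in propranolol fish within both rows of the slide, by 5.03 and 6.51 log2 units. Its adjusted p was not under 0.05 in 12 of 21 alternative fits (limma, and 1 ordinary linear model) and ranged from 0.000908 to 0.576. Its sequence is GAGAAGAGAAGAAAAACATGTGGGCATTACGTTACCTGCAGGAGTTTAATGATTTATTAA, and the files used here give no gene for it.

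UF_Ppr_AF_100234, the other probe higher in propranolol fish that the naming rule took, did not pass adjustment. It was not well above background in any of the 4 controls and was well above it in 4 of 4 propranolol fish, at processed intensities from 22.2 to 403. Its mean was -4.01 ± 1.58 in propranolol fish and -8.67 ± 0.24 in controls (SD, n = 4 each), with an adjusted p of 0.221 on these values (limma). With dim spots raised, the level was 6.13-fold higher in propranolol fish (limma, adjusted p = 0.594). Propranolol 1 lay at -1.77 and the other propranolol fish between -5.45 and -4.23. Without propranolol 1, the log2 fold change on the unraised values was 3.92, against 4.66 with all fish. With normexp, the log2 fold change of the probe was 1.43. Its sequence is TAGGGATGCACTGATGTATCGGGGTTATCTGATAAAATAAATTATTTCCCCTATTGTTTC.

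The rule took 2 probes with lower values in propranolol fish, and neither passed adjustment. UF_Ppr_AF_114722 was well above background in all 8 fish, with means of 1.36 ± 0.77 in controls and -1.74 ± 1.90 in propranolol fish (SD, n = 4 each). Its log2 fold change was -3.10 with a standard error of 0.87 (limma, adjusted p = 0.615). The size varied between fish, with -5.11 in slide row 1, -1.09 in slide row 2 and -2.39 without propranolol 3. Its sequence is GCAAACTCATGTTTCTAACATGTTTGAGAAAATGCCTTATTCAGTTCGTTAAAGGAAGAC. UF_Ppr_AF_118113 had means of -4.76 ± 0.39 in controls and -7.79 ± 1.24 in propranolol fish (SD, n = 4 each). It was well above background in 4 of 4 controls and 1 of 4 propranolol fish, and its log2 fold change was -3.03 with a standard error of 0.56 (limma, adjusted p = 0.488). That size rests on values not well above background in 3 propranolol fish. It was -1.66 with dim spots raised, -0.69 with normexp, -4.11 in slide row 1 and -1.95 in slide row 2. Its sequence is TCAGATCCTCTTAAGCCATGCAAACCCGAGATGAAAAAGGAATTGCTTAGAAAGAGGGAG.

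**Figure D2:**
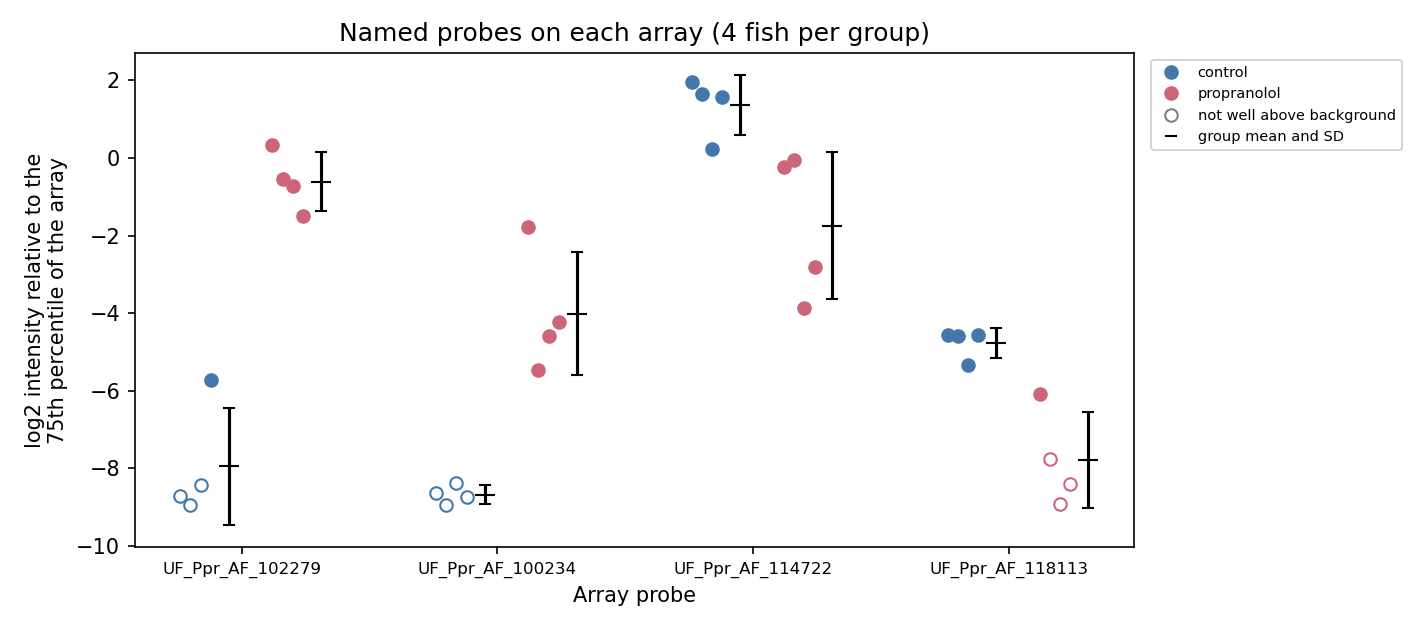
Log2 intensity relative to the 75th percentile of the array (vertical) for the 4 named probes (horizontal), with a point for each fish and the group mean and SD beside the points. Open points were not well above background. The 4 propranolol values of UF_Ppr_AF_102279 reach 0.33 and all lie above its control values, which run from -8.94 to -5.72.

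At an unadjusted p under 0.05, limma counted 823 probes (7.22% of those tested), 368 higher and 455 lower in propranolol fish, where chance alone gives about 570.3. The larger side turned with the scaling: quantile normalization counted 467 higher and 410 lower, and median centring 416 and 406. With a fold of at least 1.5 as well, 609 probes remained, 243 higher and 366 lower, and lower values stayed the larger part under all 4 other scalings or starting values. The larger side turned between slide rows, with 188 higher and 581 lower in row 1 alone and 249 higher and 185 lower in row 2 alone. The groups did not overlap for 423 probes (3.71%), against a chance share of 2.86%, and 9 of the 35 splits of the 8 arrays gave as many (highest other 581). Filtering probes by the real groups can raise the number for the real split.

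The single adjusted call depended on the fit. Counts at the adjusted threshold were 0 with slide row as a block, 0 with no filter on dim probes, 0 with a filter asking for all 8 arrays and 0 with an ordinary linear model. With the row block, no filter and the ordinary model, the adjusted p of UF_Ppr_AF_102279 was 0.177, 0.0903 and 0.284. Its log2 fold change was 7.34 in each by construction, since they use the same values and the rows are balanced. The filter on all 8 arrays removed the probe. Its log2 fold change was 7.01 to 8.08 with 1 fish left out. Leaving out 1 fish at a time gave 0 to 6 calls. The count was 0 without control 1, control 2, control 3, propranolol 2 or propranolol 4, 3 without control 4 and 6 without propranolol 1. Without propranolol 3 it was 1, and that call was lower in propranolol fish, so a different probe.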

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

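The tests of explanations in this part were chosen after the results had been seen, and so were the alternatives with slide row or raised dim spots. Outlying fish were searched for in 14 sets of 4 values, and chance marks about 1 set in 20. In UF_Ppr_AF_102279, control 4 lay at -5.72 while the other controls lay between -8.94 and -8.43. Only control 4 was well above background among the controls, so the size of that gap rests on dim values. In UF_Ppr_AF_118113, control 3 lay at -5.34 while the other controls lay between -4.58 and -4.55.

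The rise of UF_Ppr_AF_102279 was weighed against 3 explanations. Substitute values for dim spots were argued against as the whole cause by a log2 fold change of 5.77 with dim values raised to the lowest well-above-background signal, against 7.34 without. Slide row was argued against by the balanced design only: each row holds 2 control and 2 propranolol arrays, so a shift between rows cancels. The differences of at least 5.03 log2 units within each row, with dim values raised, add no evidence. The groups then lay 4.22 log2 units apart at the closest, so each within-row difference had to be large. Slide column, which is partly tied to the groups, was not tested. Whether the probe passed adjustment depended on the fit (limma, adjusted p from 0.000908 to 0.576 over the alternatives). On and off variation between fish that follows the groups by chance stays open. Of 139 probes with an 8-fold or larger gap between fish, 9 were on in 4 fish and off in 4. Of these 9, 1 followed the groups. The chance that at least 1 of 9 would do so was 0.23 if probes vary independently and all splits are equally likely. Controls 1 and 2 stood apart together more often than equal chances give, so 0.23 is only a rough guide. An effect of propranolol stays open too and was not tested separately from that chance.

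The separation of whole profiles (exact permutation p = 0.0286) was weighed against 3 explanations. The likeness of controls 1 and 2 cannot be told apart from the groups here: the real split was the 1 with the highest pseudo-F of the 15 that keep them together (1.46, highest other 1.43), too few splits for a share under 0.05. The part of probes near or below background cannot be settled. The exact permutation p was 0.2 over probes well above background on all 8 arrays, but also 0.171 with no filter, which adds dim probes. Neither of these filters uses the groups, whereas that of the main test does. A small share of widely varying probes may carry part of the separation, with an exact permutation p of 0.0857 without the 5% of probes with the largest SD. Slide column, which is partly tied to the groups, was not tested as an explanation. An effect of propranolol stays open beside these.

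Controls 1 and 2 were the most alike pair of arrays (r = 0.978). Their deviations from the group mean correlated at 0.116 across the 11406 tested probes, where 4 independent fish give about -0.333 and the next pair of 1 group had -0.0672. They stood apart together from the other 6 fish in 11 of the 32 on and off probes that parted a pair from the rest, where equal chances give 1.14 for each pair. Shared on and off probes alone were argued against, since over the 10229 probes without a 2-fold gap the correlation was 0.0831 and that of the next pair -0.142. No biological explanation was tested, and what the pair shared is not recorded in the labels.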

How the results depend on the processing

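The tests added after the data had been examined were slide row as a block, each row alone, raised dim spots, the test of whole profiles and the refits over other splits of the fish. Chance could not be excluded for any of the 3 counts of probes, although filtering by the real groups can favour the real split. A count at the adjusted threshold of at least 1 came from 6 of the 35 splits (real 1, highest other 5), a count at unadjusted p of at least 823 from 5 (highest other 974), and a count with 1.5-fold of at least 609 from 3 (highest other 644). The split with 5 adjusted calls set controls 1 and 2 and propranolol 1 and 4 against the rest; whether it marks a structure was not tested. The split by slide row gave 0, 426 and 277.

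The adjusted count, 1 as reported, was 0 with no filter, with the filter on all 8 arrays, with the ordinary model and with slide row as a block, and 2 with trend and robust, of which 1 was the same probe. It was 1 in each slide row alone, where UF_Ppr_AF_102279 was not called, and 1 in the other settings with all fish, apart from the replicate block. Leaving out 1 fish gave 0 to 6. The count at unadjusted p was 654 to 1114 with 1 fish left out and 434 in slide row 2 alone (769 in row 1). With 1.5-fold it was 361 with normexp, 371 with the ordinary model and 542 to 880 with 1 fish left out. The rest of these totals stayed within 1.5 times. Without propranolol 1, 415 probes were higher and 699 lower at unadjusted p, and 288 and 592 with 1.5-fold.

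The exact permutation p for whole profiles was 0.114 with normexp, 0.171 with no filter, 0.2 with the filter on all 8 arrays, 0.0571 with raised dim spots, 0.0857 without the most variable 5% of probes and 0.0286 to 0.114 with 1 fish left out.

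The 4 named probes kept their direction in every fit that tested them. The filter on all 8 arrays removed 3 of them. UF_Ppr_AF_100234 and UF_Ppr_AF_118113 passed adjustment only without propranolol 1 (limma, adjusted p = 0.0131 and 0.0269).

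Replicate numbers were not taken to pair the fish. Same-numbered deviations correlated at 0.048, 0.0501, 0.124 and 0.00971, only 1 of them over 0.1, although 5 of 8 fish correlated best with their own number, where chance gives about 2. With the replicate block, 0 probes passed (smallest adjusted p = 0.576), and 866 and 672 met the unadjusted thresholds. The slide or scan block and all tests of gene lists were not run. Dim signal limited 3 of the 4 named probes. The cause of the shifts above was not tested.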

Other observations

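All tests in this part were chosen after the results had been seen. Of 13488 probes that were well above background in at least 1 fish and had a value in all 8, 139 showed an 8-fold or larger gap between fish, with dim values raised to the lowest well-above-background signal. In 48 of these a single fish was on, and in 37 a single fish was off. Control 1 stood apart alone in 31 probes, propranolol 1 in 16, propranolol 4 in 14 and control 2 in 0. With a 4-fold gap there were 369 such probes, 13 of them on in 4 fish, and with a 16-fold gap 72 and 5. At each of the 3 gaps 1 probe followed the groups.

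For 709 contig or sequence names the array held a pair of probes, and 1 of each pair had a name ending in ms. The ms probes were tested less often, 51.6% against 76.4% of their partners. In 283 pairs both were tested, and their log2 fold changes correlated weakly across pairs (Pearson's r = 0.190, permutation p = 0.00159; Spearman's rho = 0.184, permutation p = 0.00173; 100000 resamples, two-sided). Probes are not independent replicates, so these p-values describe the pairs on these 8 arrays. The sign was shared in 156 of the 283 pairs. Mean levels of partners correlated little over all pairs (Spearman's rho = 0.0846).

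A hypothesis was that ms probes may lie on the opposite strand of their partner. A shared stretch of 20 bases was found in 0 pairs on the same strand and in 7 on opposite strands. The motif AATAAA, which marks the 3' end of many sense transcripts, argued against it as a general rule among the probes that could be read this way. It made up 67.2% of ms probes that held only 1 of AATAAA and its reverse complement TTTATT (43 against 21). Among their partners it made up 72.9% (105 against 39, Fisher's exact p = 0.411). These are a small part of the 709 pairs, so the other pairs are not covered. Whether the low correlation of mean levels and the smaller share of ms probes tested reflect strand was not tested. The 7 overlapping pairs stay unexplained by that result.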
